A study of Mus musculus with 12 samples.

How the data were processed

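Total RNA was taken with Trizol from livers of C57BL/6 mice aged 20 weeks and sequenced after preparation with an Illumina TruSeq RNA kit, as the labels give. The 12 libraries form 4 groups of 3 (female and male, WT and ARE-Del). The deposited RPKM values were made by the authors, per the submitters' processing notes, with Trimmomatic 0.30 for trimming, TopHat2 2.0.8 for alignment to the mm9 assembly, and Partek and GenomeStudio 6.6 for quantification. How reads were counted and whether strand was used are not given in the sources used here. Raw reads were not used here.

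The table held 19852 genes with unique identifiers, so no symbol needed its values combined. Of these, 401 identifiers join at least 2 symbols and 19 read as dates, and such entries were kept as listed. Values between 0 and 1e-06 made up 2.26% of the table. Read totals were not used here. Ratios of low values to those of female WT 1 were taken over genes below 0.2 RPKM in both libraries. Outside female WT 1, 11.5% to 15.3% of these genes lay at the commonest ratio (tolerance 0.02 log2). Relative depth was estimated from that ratio. It was 1, 0.948 and 1.09 in female WT, 1.45, 1.16 and 1.14 in female ARE-Del, 1.36, 0.909 and 1.02 in male WT and 1.17, 1.19 and 1.4 in male ARE-Del, relative to female WT 1. Tested genes had a median SE of 0.0813 on the log2 scale for a difference between 2 groups and of 0.115 for the interaction. The 20 highest genes took 33.8% to 38.5% of summed RPKM per library.

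Genes with RPKM of at least 0.5 in at least 3 libraries were tested (10568). A gene can pass through 1 group alone, so low genes that are high in 1 group are more likely to be tested. Counts and tests of lists with many low members lean towards that group. Log2(RPKM + 1) was fitted with limma 3.58.1 in R 4.3.3 as 4 group means over 12 libraries, with moderated variances that follow the mean (eBayes with trend) and Benjamini-Hochberg adjustment within each of 5 comparisons at 0.05. The comparisons were ARE-Del against WT in each sex, their difference (the interaction), and females against males in each genotype. The scaling of the values was left as deposited. Errors of log2 changes are SE and those of RPKM are SD over 3 libraries. A log2 change on this scale is smaller than the log2 ratio for genes near or below 1 RPKM. Figures were drawn with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

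The 33 fixed gene lists (IFN-gamma-induced genes, type I interferon-induced genes, MHC class I antigen presentation, MHC class II antigen presentation, chemokines and adhesion molecules, T cell markers, NK and cytotoxic markers, B and plasma cell markers, Kupffer cell markers, monocyte and macrophage markers, neutrophil markers, erythroid markers, cholangiocyte markers, stellate cell and matrix genes, endothelial markers, cell cycle genes, bile acid synthesis, bile acid and bile lipid transport, cholesterol biosynthesis, fatty acid synthesis, fatty acid oxidation and PPAR-alpha targets, xenobiotic cytochrome P450 genes, male-biased liver genes, female-biased liver genes, growth hormone signalling, sex steroid receptors and metabolism, acute phase genes, complement genes, hepatocyte identity genes, cell death genes, immediate early and heat shock genes, pancreatic acinar markers and adipocyte markers) held 545 entries. Of these 458 matched a table identifier, 14 an older symbol, 17 a synonym and 14 a merged entry, while 7 merged with an unrelated gene and 35 without a match were left out. The 27 lists with at least 5 tested members were tested with camera (preset correlation 0.01) and adjusted over the lists, and again with the correlation estimated from the data. Member counts are given both at the adjustment over all genes and adjusted over the list alone. Single values below the filter were compared by exact permutation, and list means per library by t tests within the 4 groups (8 degrees of freedom). Overlaps were tested by Fisher's exact test.

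The lists, filter, model, comparisons, alternatives and rule for named genes were set before the data were examined. The rule names Ifng and the sex-chromosome genes. It adds the called genes with the largest rise and fall in each genotype comparison (6 each way) and the largest difference in each sex comparison (5 each way), in both cases with groups that do not overlap, which chance alone gives in 10% of genes for 3 against 3. For the interaction it names the called genes with the smallest p (8 each way). From each list it takes the 3 members with the largest change in females among those called in either sex, filled up by the highest RPKM, and not all of these are printed. Gene models without a name and receptor segments were left out of all but the lists. Some genes that the rule or the lists name are not reported here, though they stay in all counts. Genes outside this rule were named after their values were seen: Zap70, Cxcl11, Tlr1, Tlr2, Tlr4, Tlr5, Tlr9, Ctsb, Ctsc, Clec7a, Clec4a1, Ugt2b34, Ugt2b36, Cd163, Selenbp2, C6, the merged Cyp2d9 entry, Ugt2b38, the merged Cyp2c40 entry, Por, Hspa1b, Hsd17b6, Ostb, Cyp27a1, Cyp2c70, Ccbl2, Sult3a1, Ccl8, Itgax and Ms4a7, and Serpina1e for the interaction. Hod, Mod1, Igj, Cdc2a, Ela1, Jarid1d and Ccbl2 are older symbols for Hopx, Me1, Jchain, Cdk1, Cela1, Kdm5d and Kyat3. Reads shared between close copies (the Mup, Serpina1, Cyp and MHC genes) make their single values uncertain.

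Equal replicate numbers were checked as a sign of pairing. Of 18 same-numbered pairs of libraries, 5 correlated above 0.1 once group means were removed (range -0.29 to 0.24), so the numbers were not taken to pair samples. The pipeline was tested on simulated data built on the same design with 50 genes seeded at each size. Seeded genes had a mean log2(RPKM + 1) of at least 1, and all other genes carried independent noise without a group effect. The shares and false calls below need not hold for lower genes or where many correlated genes change. In the female comparison 78% of genes changed by 0.5, 96% changed by 1 and 100% changed by 2 on the log2 scale were called, with 12 false calls, and in the interaction 44%, 88% and 100%, with 8 false calls. The alternatives were a pseudocount of 0.1, no filter, a filter at 1 RPKM, median-of-ratios scaling, quantile normalization, a replicate block, library weights, robust moderation, only the groups compared, a fold threshold, the estimated correlation and the omission of each library in turn.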

Results

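The series measured liver transcripts by RNA sequencing in C57BL/6 mice aged 20 weeks. The libraries fell into 4 groups of 3, female and male wild-type (WT) littermates and female and male ARE-Del mice. The ARE-Del allele removes the AU-rich element of the 3′ untranslated region of Ifng, a sequence that shortens the life of its mRNA, and the series used these mice as a model of lasting interferon-gamma (IFN-gamma) expression. The deposited table listed RPKM (read counts scaled to transcript length and library total) for 19852 genes in all 12 libraries, of which 10568 passed the filter on low values and were tested. Summed RPKM ran from 173476 to 208647 per library. Read totals are not given in the sources used here. From the commonest ratio of low values, each library's depth was estimated at 0.909 to 1.45 times that of female WT 1. Albumin (Alb) took 13.8% to 16.5% of summed RPKM in the female libraries and 8.56% to 12.5% in the male libraries. Within a group, libraries correlated across genes at r = 0.993 to 0.996. The labels do not say beyond n = 3 that the samples are separate animals. The p-values of limma, t tests and permutation therefore measure only the spread between these samples. Those of camera with the preset correlation and of Fisher's test set genes against other genes. They do not measure replication between livers.

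**Figure D1:**
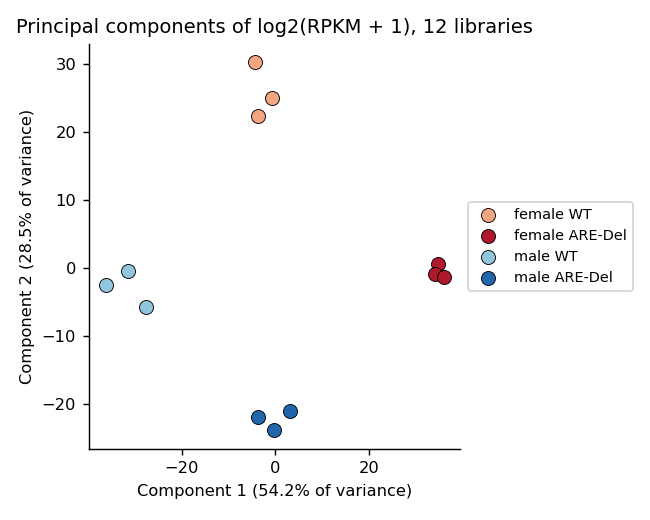
Principal components of log2(RPKM + 1) over the 10568 tested genes, with 1 point per library coloured by group. Component 1 (54.2% of the variance) and component 2 (28.5%) place the 3 libraries of each group beside each other and the 4 groups apart.

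Ifng itself, the gene carrying the deletion, was low in every library and below the filter. Its RPKM was 0.0208, 0.011 and 0.0096 in the female WT libraries and 0.208, 0.0898 and 0.238 in the female ARE-Del libraries. In males it was 0.0382, 0 and 0 in WT, where 0 is a value as listed, and 0.0978, 0.122 and 0.0742 in ARE-Del. All 6 ARE-Del libraries lay above all 6 WT libraries, and an exact stratified permutation test of genotype within sex gave p = 0.005 (2-sided), the smallest its 400 arrangements allow. Within 1 sex an exact permutation test of 3 against 3 libraries cannot go below p = 0.1, which both sexes reached. The gene-level value does not show the deleted element itself. The Y-linked genes Ddx3y, Kdm5d (listed as Jarid1d), Uty and Eif2s3y matched the sex labels. Ddx3y was listed at 0 in all 6 female libraries and averaged 10 ± 0.475 RPKM (SD, n = 3) in male WT and 11.4 ± 2.07 in male ARE-Del. Kdm5d averaged 0.705 ± 0.115 and 0.883 ± 0.0667, Uty 0.852 ± 0.131 and 1.06 ± 0.162, and Eif2s3y 6.93 ± 0.486 and 6.66 ± 0.964 in the same groups, against at most 0.0055 in any female library. Xist, the RNA that silences an X chromosome in females, was between 33.0 and 45.6 RPKM in 5 female libraries but 0.046 in the library labelled female ARE-Del 2, which carried no Ddx3y.

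**Figure D2:**
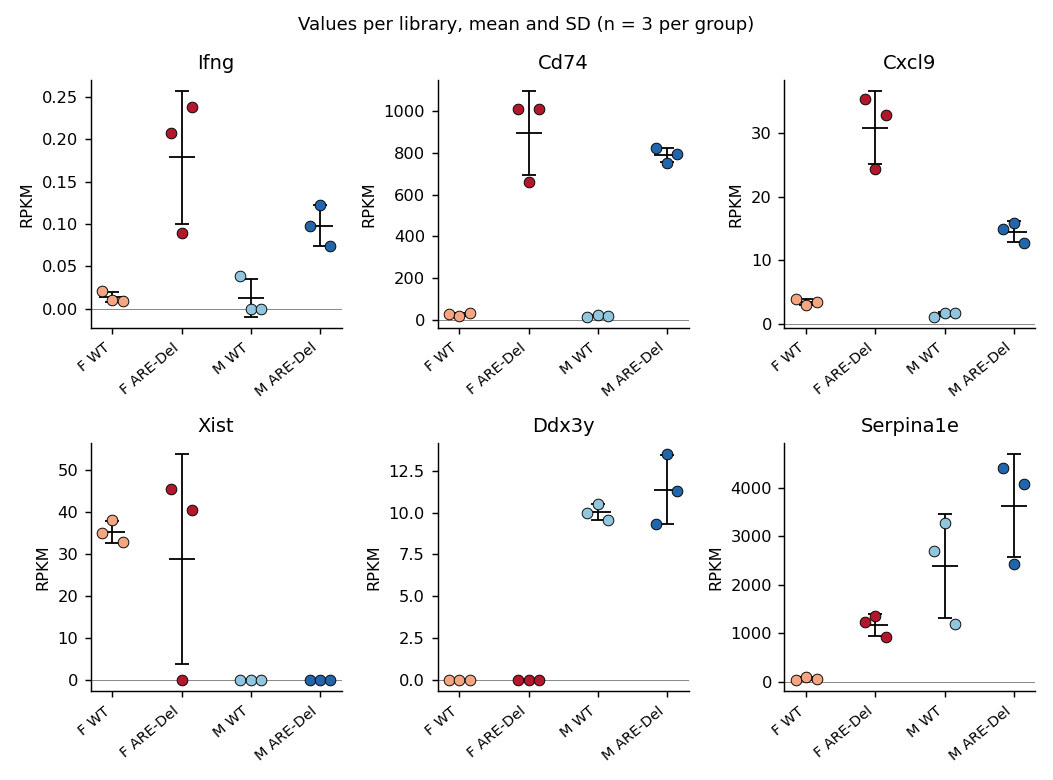
RPKM of 6 genes in each library (points), with the group mean and SD (n = 3 per group; F female, M male). Ifng, Cd74 and Cxcl9 were higher in all ARE-Del libraries than in all WT libraries. Xist was near 0 in the library labelled female ARE-Del 2, Ddx3y was listed at 0 in every female library, and Serpina1e was lowest in female WT.

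The comparison of ARE-Del with WT in females asked which liver transcripts change with lasting IFN-gamma expression in that sex. Antigen presentation genes showed the largest rises. Cd74, the invariant chain of MHC class II, averaged 23.9 ± 8.09 RPKM in WT and 895 ± 202 in ARE-Del (SD, n = 3), a log2 fold change of 5.20 ± 0.25 (SE; limma, Benjamini-Hochberg adjusted p = 1.2e-07). The class II chains H2-Eb1 (4.76 ± 0.24), H2-Aa (4.69 ± 0.27) and H2-Ab1 (4.31 ± 0.22), the lymphocyte antigen gene Ly6a (4.53 ± 0.31) and the ubiquitin-like modifier Ubd (4.44 ± 0.30) followed, with adjusted p between 1.3e-07 and 7.7e-07. The largest falls among named genes were in the major urinary protein genes Mup2 (-3.10 ± 0.41) and Mup1 (-2.84 ± 0.22), the fatty acid hydroxylase Cyp4a14 (-2.83 ± 0.43), the organic anion carrier Slco1a1 (-2.31 ± 0.40), the merged Mup3 entry (-2.18 ± 0.25) and the succinate receptor Sucnr1 (-2.17 ± 0.15), with adjusted p between 7.3e-07 and 7.8e-04. Mup genes are near-identical copies, so the split of reads among them is uncertain.

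Of the fixed lists, genes induced by IFN-gamma rose in females in 17 of 18 tested members, the same count when adjusted over the list alone, with a median log2 fold change of 2.13. The GTPase Igtp rose by 3.10 ± 0.19 and the merged Tgtp entry by 4.29 ± 0.12, while Cxcl11 did not pass (0.13 ± 0.12). All 14 tested MHC class I genes (median 1.54; Psmb9 2.53 ± 0.14, Tap1 2.33 ± 0.14), all 10 MHC class II genes (median 3.65) and all 12 chemokine and adhesion genes (median 1.5; Cxcl9 2.82 ± 0.14, Vcam1 2.04 ± 0.08) rose, with the same counts adjusted over the list alone. Genes induced by type I interferon rose in 19 of 21 (21 adjusted over the list alone and 15 under median-of-ratios scaling), with a smaller median of 0.83, led by the antiviral Oas1a (1.56 ± 0.10) and the transcription factor Irf7 (1.47 ± 0.16). Camera, which compares a list with all other genes, gave adjusted p = 6.5e-15 for the IFN-gamma list, 1.2e-08 for type I interferon, 2.8e-12 for class I, 5.0e-11 for class II and 1.2e-08 for chemokines. With an estimated correlation the adjusted p was 0.103 for all of these except type I interferon (0.193), so none passed.

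Markers of blood-borne and resident immune cells rose in female ARE-Del livers. All 12 monocyte and macrophage markers rose (median 1.77; the Fc receptor Fcgr4 3.10 ± 0.26, the pore-forming Mpeg1 2.85 ± 0.20). Of 12 Kupffer cell markers 10 rose (median 1.52; the scavenger receptor Marco 3.09 ± 0.50, the complement chain C1qb 2.17 ± 0.17) and Cd163, a haemoglobin scavenger receptor, fell (-1.48 ± 0.32). T cell markers rose in 6 of 7 (median 0.78; Cd8a 1.06 ± 0.15, Cd3g 0.82 ± 0.11) and the kinase Zap70 fell (-0.29 ± 0.08). All 6 NK and cytotoxic markers rose (median 1.09; the granzymes Gzmb 1.45 ± 0.11 and Gzma 1.43 ± 0.09). These counts did not change when adjusted over the list alone. Many T cell, NK, B cell and chemokine entries were below the filter and not tested. Since 1 group alone can pass a gene, low markers raised in ARE-Del are more likely to be tested. The counts of these lists therefore lean towards rises. By camera the adjusted p was 8.5e-10 for monocytes, 8.6e-04 for Kupffer cells, 0.00983 for T cells and 5.9e-05 for NK cells. Estimating the correlation gave an adjusted p of 0.103 for monocytes and NK cells and 0.379 for Kupffer and T cells. Lists with under 5 tested members had no camera test. Of these, B and plasma cell markers rose in 3 of 4 (4 adjusted over the list alone; the joining chain Igj 1.11 ± 0.28), neutrophil markers in 2 of 3 (3 adjusted over the list alone; S100a8 0.94 ± 0.27) and cholangiocyte markers in 2 of 4, with 2 adjusted over the list alone (Sox9 0.57 ± 0.10). None of 4 erythroid markers passed on either adjustment (median -0.19, for example Hba-a1 -0.21 ± 0.31). The acinar marker Ela1 fell (-0.88 ± 0.10), and of 2 adipocyte markers Lipe rose (0.49 ± 0.10) and Pparg did not pass (-0.19 ± 0.13), on both adjustments.

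The stellate and matrix, cell cycle, endothelial, and immediate early and heat shock lists did not pass camera in females. Stellate cell and matrix genes rose in 7 of 12 members (8 adjusted over the list alone), among them the collagen Col3a1 (0.82 ± 0.19), with a list median of 0.51 and camera adjusted p = 0.0756, or adjusted p = 0.544 with an estimated correlation. Cell cycle genes rose in 5 of 7 on either adjustment (Mki67 0.63 ± 0.12; median 0.39, adjusted p = 0.0525 and estimated-correlation adjusted p = 0.482). Endothelial markers rose in 3 of 11 on either adjustment (Lyve1 1.59 ± 0.23), with a median of 0.11 that turned to -0.01 under median-of-ratios scaling (adjusted p = 0.927, estimated-correlation adjusted p = 0.981). The immediate early and heat shock list rose in 4 of 9 on either adjustment (Atf3 1.08 ± 0.12, Jun 0.71 ± 0.13; median 0.66, adjusted p = 0.0756, estimated-correlation adjusted p = 0.365).

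Among liver-secreted defence proteins and cell death genes, acute phase genes rose in 14 of 24 on either adjustment (12 under median-of-ratios scaling; median 0.88), with wide spread in the metallothionein Mt2 (3.07 ± 0.92) and in Lcn2 (2.45 ± 0.77). Complement genes rose in 12 of 18 (14 adjusted over the list alone, and 9 with 1 falling under that scaling; median 0.51), such as the inhibitor Serping1 (0.98 ± 0.13) and C2 (0.96 ± 0.12). Cell death genes rose in 15 of 17 (16 adjusted over the list alone and 12 under that scaling; median 0.76), led by the nucleic acid sensor Zbp1 (2.43 ± 0.10), the necroptosis effector Mlkl (1.58 ± 0.11) and Casp1 (1.52 ± 0.11). Camera gave adjusted p = 0.0249 for acute phase, 0.0073 for complement and 2.2e-08 for cell death genes. When the correlation was estimated the adjusted p was 0.544, 0.449 and 0.103. The acute phase call rested in part on 1 library, with adjusted p = 0.345 without the library labelled female ARE-Del 2 and a call in 10 of the 12 settings that leave out 1 library. Complement and cell death were called in all 12.

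Of the metabolic lists in females, fatty acid oxidation and PPAR-alpha targets fell in 7 of 18 (adjusted over the list alone 10 fell and 1 rose, and under median-of-ratios scaling 15 fell; median -0.35), including the pantetheinase Vnn1 (-1.70 ± 0.36) and the thioesterase Acot1 (-1.44 ± 0.28). Xenobiotic cytochrome P450 genes fell in 9 of 16 (10 adjusted over the list alone and 11 under that scaling; median -0.35), such as Cyp2e1 (-0.81 ± 0.15) and Cyp2c37 (-0.76 ± 0.10). Genes with female-biased liver expression fell in 7 of 17 and rose in 1 (8 and 1 adjusted over the list alone; median -0.79). Cyp3a44 (-1.60 ± 0.34) and Hao3 (-1.21 ± 0.30) fell, and the proton pump subunit Atp6v0d2 rose (1.95 ± 0.31). Male-biased genes went both ways, 4 up and 4 down of 16 on either adjustment (median -0.16). The protease inhibitor Serpina1e rose from 67.3 ± 27.7 to 1173 ± 222 RPKM (4.17 ± 0.38), with Selenbp2 (1.63 ± 0.50), C6 (1.46 ± 0.23) and the merged Cyp2d9 entry (0.69 ± 0.24), while Mup1, Slco1a1, the merged Mup3 entry and the elongase Elovl3 (-1.18 ± 0.26) fell. Serpina1 genes are near-identical copies and their values are uncertain. For these lists camera's adjusted p was 2.2e-08 for fatty acid oxidation, 8.1e-08 for P450, 4.9e-05 for female-biased and 0.0112 for male-biased genes. With an estimated correlation the adjusted p was 0.201, 0.103, 0.103 and 0.427.

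Smaller shifts were seen in bile acid and steroid handling in females. Bile acid synthesis genes fell in 4 and rose in 2 of 14 on either adjustment (the oxysterol hydroxylase Cyp39a1 -1.11 ± 0.23, Akr1c6 -0.57 ± 0.11, Acox2 0.41 ± 0.08; median -0.18). Bile acid and bile lipid transport genes fell in 3 of 16 on either adjustment (Slco1a1, Slco1a4 -1.30 ± 0.13 and Slco1b2 -0.69 ± 0.10; median -0.17). Sex steroid receptors and metabolism fell in 5 and rose in 1 of 10 on either adjustment (Ugt2b5 -0.94 ± 0.15; median -0.33). Of 13 fatty acid synthesis genes 1 fell on either adjustment, malic enzyme Mod1 (-1.60 ± 0.22; list median -0.10). The camera adjusted p was 0.00864, 6.5e-04, 0.00136 and 0.018 for these lists, and with an estimated correlation the adjusted p was 0.103, 0.103, 0.103 and 0.482. Cholesterol biosynthesis rose in 2 of 20 (Dhcr7 0.62 ± 0.21, Srebf2 0.38 ± 0.13; none adjusted over the list alone), growth hormone signalling rose in 3 and fell in 1 of 13 on either adjustment (Igfbp1 2.90 ± 0.39, Ghr -0.43 ± 0.09), and hepatocyte identity genes rose in 1 and fell in 2 of 18 (Apoa1 0.82 ± 0.14, Cebpa -0.35 ± 0.11; 1 and 0 adjusted over the list alone). For these lists the medians (0.23, 0.22 and 0.04) and means (0.24, 0.27 and 0.03) were positive while camera ranked them below other genes (adjusted p = 0.927, 0.46 and 0.0756, and with an estimated correlation adjusted p = 0.981, 0.663 and 0.427). Under median-of-ratios scaling 6 bile acid synthesis, 6 transport, 3 fatty acid synthesis and 6 hepatocyte identity genes fell, and 0 cholesterol genes rose. Fatty acid synthesis was called in 10 of 12 settings that leave out 1 library and 16 of 22 alternatives in all. The hepatocyte identity median was -0.08 under median-of-ratios scaling and -0.01 under quantile normalization.

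In all, limma called 3306 of 10568 genes between female ARE-Del and WT at an adjusted p below 0.05, 2722 up and 584 down, of which 450 changed by at least 1 on the log2 scale. Without the library labelled female ARE-Del 2, which lacks Xist, 3163 genes were called. Camera called 20 of the 27 lists tested, 12 up and 8 down, and 0 with an estimated correlation. The split between rises and falls depended on scaling. Of the calls, 82.3% were up as deposited, 58.1% of 3591 under median-of-ratios scaling and 39.3% of 4113 under quantile normalization. The median log2 fold change of all genes was 0.09 as deposited and -0.07 after quantile normalization, a shift of -0.16, so small changes are better read relative to the median gene. On that footing the medians were 2.04 for the IFN-gamma list, 1.68 for monocyte markers, 0.42 for complement, -0.44 for fatty acid oxidation, -0.44 for P450 and -0.87 for female-biased genes.

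**Figure D3:**
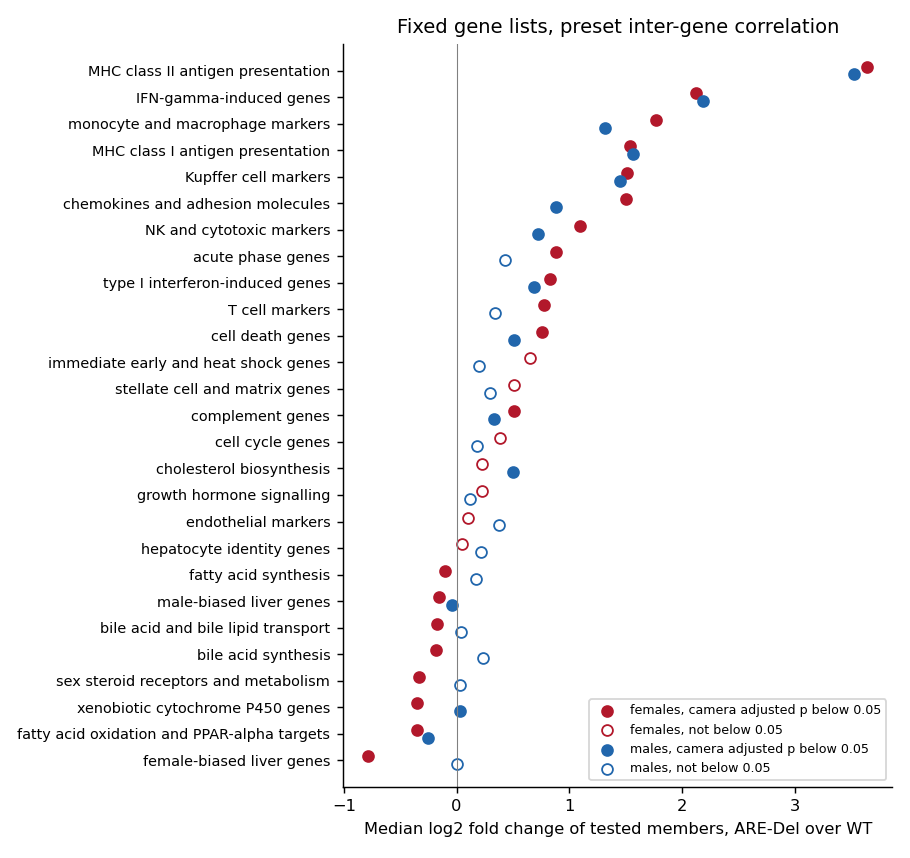
Median log2 fold change of the tested members of each of 27 fixed lists (ARE-Del over WT, log2(RPKM + 1) scale) in females (red) and males (blue). Filled points have a camera adjusted p below 0.05 with the preset correlation of 0.01, and none has one with an estimated correlation. MHC class II genes lie highest in both sexes, and female-biased liver genes lie lowest in females.

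The same comparison in males asked which liver transcripts changed with the allele in that sex. Cd74 rose from 17.8 ± 4.38 to 790.1 ± 35.2 RPKM (SD, n = 3), a log2 fold change of 5.42 ± 0.25 (SE; limma adjusted p = 9.0e-08). H2-Aa (4.81 ± 0.27), the merged Tgtp entry (4.70 ± 0.12), H2-Eb1 (4.57 ± 0.24) and Ly6a (4.38 ± 0.31) rose with adjusted p between 6.0e-10 and 2.0e-06. The mucosal trefoil peptide Tff3 rose from 0.493 ± 0.13 to 46 ± 32.8 RPKM (4.61 ± 0.53, adjusted p = 8.6e-05). Its 3 female WT libraries were listed at 0 and the female ARE-Del libraries at 6.43, 16 and 5.65. The largest falls were in the lipocalin Lcn13 (-2.17 ± 0.20), Mup2 (-1.75 ± 0.41), Cyp4a14 (-1.72 ± 0.43), Sucnr1 (-1.68 ± 0.15), the kynurenine aminotransferase Ccbl2 (-1.64 ± 0.15) and the organic anion carrier Slc22a7 (-1.63 ± 0.24), with adjusted p between 1.2e-05 and 0.0143.

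In males 17 of 18 IFN-gamma-induced genes rose on either adjustment (median 2.19; Igtp 4.07 ± 0.19), and Cxcl11 did not pass (0.04 ± 0.12). All 14 MHC class I genes (median 1.57; Psmb8 2.54 ± 0.13, Psmb9 2.53 ± 0.14) and all 10 class II genes (median 3.53) rose, with the same counts adjusted over the list alone. Type I interferon genes rose in 15 of 21 (18 adjusted over the list alone; median 0.69; Irf7 1.34 ± 0.16, Oasl2 1.17 ± 0.11), and chemokine and adhesion genes in 11 of 12 on either adjustment (median 0.88; Cxcl9 2.61 ± 0.14, Vcam1 1.80 ± 0.08). Cell death genes rose in 14 of 17 on either adjustment and in 11 under median-of-ratios scaling (median 0.51; Zbp1 2.20 ± 0.10, Mlkl 1.79 ± 0.11). Camera's adjusted p was 2.1e-20 for the IFN-gamma list, 3.0e-19 for class I, 1.6e-14 for class II, 2.1e-09 for type I interferon, 3.3e-07 for chemokines and 2.0e-08 for cell death. The estimated correlation gave an adjusted p of 0.114 for the IFN-gamma, class I, class II and cell death lists, 0.265 for type I interferon and 0.139 for chemokines.

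Immune cell markers rose in male ARE-Del livers, among those that passed the filter, which leans towards rises as in females. Monocyte and macrophage markers rose in 11 of 12 (12 adjusted over the list alone; median 1.32; Mpeg1 2.84 ± 0.20, Fcgr4 2.34 ± 0.26), Kupffer cell markers in 9 of 12 (10 adjusted over the list alone; median 1.45; Marco 3.24 ± 0.50, Cd5l 1.89 ± 0.24) and NK and cytotoxic markers in 5 of 6 (6 adjusted over the list alone; median 0.72; Gzmb 1.36 ± 0.11). In the camera test the adjusted p was 6.4e-09, 2.3e-06 and 3.9e-05, and with an estimated correlation the adjusted p was 0.176, 0.338 and 0.176. T cell markers rose in 5 of 7 (adjusted over the list alone, 6 rose and 1, Zap70 at -0.22 ± 0.08, fell; median 0.34), without passing camera (adjusted p = 0.259, estimated-correlation adjusted p = 0.799). B and plasma cell markers rose in 3 of 4, neutrophil markers in 1 of 3 (Csf3r 0.41 ± 0.11) and cholangiocyte markers in 1 of 4 (Sox9 0.48 ± 0.10), all on either adjustment. No erythroid marker of 4 passed on either adjustment (median -0.44). Ela1, the acinar marker, fell (-0.76 ± 0.10), and Pparg of the 2 adipocyte markers fell (-0.95 ± 0.13), with Lipe (0.25 ± 0.10) passing only when adjusted over the list alone. Stellate cell and matrix genes rose in 4 of 12 (6 adjusted over the list alone; Tgfb1 0.42 ± 0.10), endothelial markers in 1 of 11 (Lyve1 1.61 ± 0.23), cell cycle genes in 1 of 7 (Mcm6 0.39 ± 0.12) and the immediate early and heat shock list in 1 of 9 (Hspa1b 0.54 ± 0.13), the last 3 on either adjustment. These lists had medians of 0.30, 0.38, 0.18 and 0.20 and did not pass camera (adjusted p = 0.247, 0.29, 0.411 and 0.919, and with an estimated correlation adjusted p = 0.799, 0.799, 0.799 and 0.95).

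The next lists in males passed camera, some of them narrowly. Cholesterol biosynthesis genes rose in 7 of 20 (9 adjusted over the list alone and 1 under median-of-ratios scaling; median 0.50), including squalene epoxidase Sqle (1.21 ± 0.26). Fatty acid oxidation and PPAR-alpha targets fell in 4 of 18 on either adjustment and in 8 under that scaling (median -0.25; Vnn1 -1.46 ± 0.36). Complement genes rose in 9 of 18 on either adjustment and in 4 under median-of-ratios scaling (median 0.33; C2 0.97 ± 0.12, Serping1 0.76 ± 0.13). Xenobiotic P450 genes rose in 2 (Cyp1a2 0.49 ± 0.14, the reductase Por 0.96 ± 0.17) and fell in 1 (Cyp2c37 -0.36 ± 0.10) of 16 on either adjustment, and camera ranked them below other genes although the median was 0.03 and the mean 0.07 (the median was -0.11, with 1 up and 3 down, under median-of-ratios scaling and -0.14 under quantile normalization). Male-biased genes fell in 2 of 16 on either adjustment (Mup1 -1.37 ± 0.22, Ugt2b38 -0.85 ± 0.24; median -0.04). Camera gave adjusted p = 0.0423 for cholesterol, 5.8e-07 for fatty acid oxidation, 0.0454 for complement, 0.0454 for P450 and 0.0121 for male-biased genes. With an estimated correlation the adjusted p was 0.799, 0.371, 0.763, 0.578 and 0.578. Of the 12 settings that leave out 1 library, 7, 12, 7, 7 and 9 called these lists.

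The remaining lists did not pass camera in males. Acute phase genes rose in 3 of 24 on either adjustment (median 0.43, adjusted p = 0.256, estimated-correlation adjusted p = 0.799), and Mt2 (2.02 ± 0.92) and Lcn2 (1.00 ± 0.77) did not pass. Hepatocyte identity genes rose in 4 of 18 (7 up and 2 down adjusted over the list alone; the gluconeogenic Pck1 1.44 ± 0.21, Apoa1 0.57 ± 0.14), and growth hormone signalling rose in 4 and fell in 1 of 13 (5 and 1 adjusted over the list alone; Igfbp1 2.37 ± 0.39, Igfbp3 0.85 ± 0.14). Bile acid synthesis rose in 3 of 14 on either adjustment (Cyp27a1 0.30 ± 0.10, Acox2 0.33 ± 0.08, Cyp2c70 0.52 ± 0.16). In transport, Ostb rose (0.45 ± 0.14; 0 adjusted over the list alone) and Slco1a4 fell (-0.70 ± 0.13), of 16. Fatty acid synthesis rose in 2 (Acacb 0.57 ± 0.17, Lpin1 1.71 ± 0.39) and fell in 1 (Mod1 -0.91 ± 0.22) of 13, female-biased genes rose in 1 of 17 (the merged Cyp2c40 entry 1.03 ± 0.16) and sex steroid genes in 1 of 10 (Hsd17b6 1.07 ± 0.24), all on either adjustment. In these 7 lists other than acute phase, the medians (0.22, 0.12, 0.23, 0.04, 0.17, 0.0040 and 0.03) and means (0.24, 0.18, 0.19, 0.02, 0.19, 0.11 and 0.16) were above 0 while camera ranked the lists below other genes. Its adjusted p was 0.937, 0.451, 0.789, 0.067, 0.36, 0.256 and 0.247, and with an estimated correlation adjusted p = 0.963, 0.799, 0.839, 0.387, 0.799, 0.763 and 0.676. Under median-of-ratios scaling the counts turned in bile acid synthesis, with 0 up and 2 down, and were 2 and 4 for hepatocyte identity, 2 and 1 for growth hormone, 0 and 2 for transport and 1 and 3 for sex steroid genes. Under quantile normalization the medians of transport (-0.09), female-biased (-0.01), growth hormone (-0.0049) and sex steroid genes (-0.09) turned negative, and under median-of-ratios scaling those of transport (-0.09) and sex steroid genes (-0.06).

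In all, limma called 2272 genes between male ARE-Del and WT, 2056 up and 216 down, of which 260 changed by at least 1 on the log2 scale. Camera called 14 of 27 lists, 11 up and 3 down, and 0 with an estimated correlation. Without male WT 1 the number of genes was 1271. Of the calls, 90.5% were up as deposited, 61.9% of 2042 under median-of-ratios scaling and 44.5% of 2076 under quantile normalization. Quantile normalization moved the median of all genes from 0.10 to -0.05, a shift of -0.14 from the unrounded medians. Relative to the median gene, the median was 2.09 for the IFN-gamma list, 0.40 for cholesterol biosynthesis, -0.35 for fatty acid oxidation and -0.07 for P450 genes.

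Most genes that rose in males also rose in females. Of 2056 genes that rose in males and 2722 in females, 1616 were shared, against 529.6 for independent lists of these sizes. Of 216 that fell in males and 584 in females, 130 were shared, against 11.9. Fisher's exact test gave p = 1e-300 (the smallest value written) and p = 1.8e-110. A gene called up in females was called down in males in 3 cases, and the reverse held in 4. Across the 10568 genes, which are not independent replicates, the female and male log2 fold changes correlated at Pearson's r = 0.846 and Spearman's rho = 0.734. The comparisons share no libraries, but the fit pools each gene's spread over all 4 groups. A gene with little spread is called more easily in both sexes, so Fisher's test does not measure shared effects alone. With each sex fitted on its own groups, 1586 genes were called the same way in both, against 1746 in the shared fit. Without male WT 1, 1099 genes were called the same way in both sexes, against 1746 with all libraries.

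**Figure D4:**
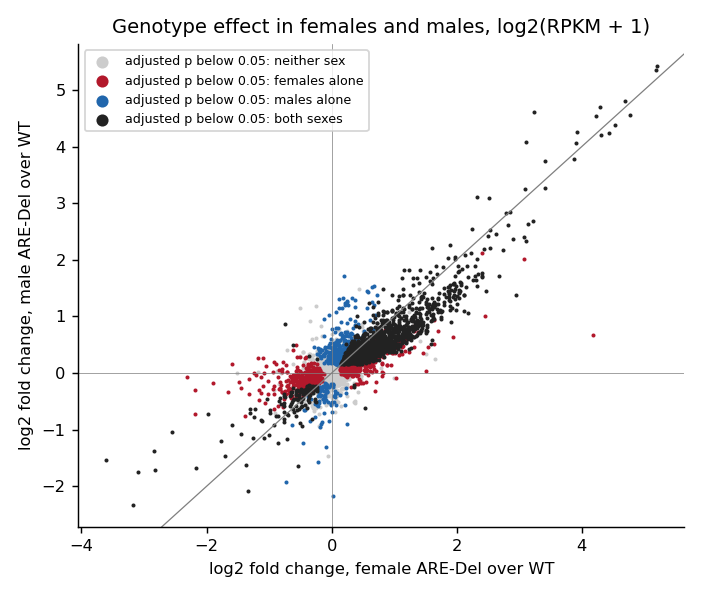
Log2 fold change of each of 10568 genes between ARE-Del and WT in females (horizontal) and males (vertical), on the log2(RPKM + 1) scale, coloured by the sexes in which the adjusted p was below 0.05. The line marks equal changes. Across genes the female and male changes correlated at Pearson's r = 0.846, which does not measure closeness to that line. Serpina1e lies to the right at 4.17 in females and 0.68 in males.

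The interaction, the female log2 fold change minus the male, tested whether the genotype effect differed between sexes. Among genes more positive in females, Clstn3, a calsyntenin, fell in males from 2.87 ± 0.518 to 0.297 ± 0.0159 RPKM and was low in females throughout (0.357 ± 0.0666 and 0.166 ± 0.034), an interaction of 1.35 ± 0.12 (SE, adjusted p = 8.2e-04). The imprinted RNA H19 rose in females from 0.106 ± 0.0168 to 2.2 ± 0.798 RPKM and stayed at 0.0764 ± 0.101 and 0.0957 ± 0.0321 in males (1.48 ± 0.19, adjusted p = 0.0104), and the basement membrane collagen Col4a3 rose in females (0.82 ± 0.07) but not in males (0.0011 ± 0.07; interaction 0.82 ± 0.10, adjusted p = 0.0104). Lcn13 fell in males (interaction 2.18 ± 0.28), while its female WT libraries were listed at 0 and its female ARE-Del libraries at 0.0352, 0 and 0. The melatonin receptor Mtnr1a (0.70 ± 0.09), Aatk (0.56 ± 0.08), Tsc22d1 (0.77 ± 0.11) and Unc119 (0.56 ± 0.08) completed the 8 with the smallest p, all at adjusted p up to 0.0163. Serpina1e, which rose in females and did not pass in males, also differed (3.49 ± 0.54, adjusted p = 0.0204), and Ccbl2 fell less in females (1.10 ± 0.21, adjusted p = 0.0465).

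More negative in females were the sialyltransferase St3gal6 (-0.51 ± 0.07), Pcp4l1 (-1.26 ± 0.20), the female-biased Cyp2b13 (-1.05 ± 0.17, with male ARE-Del libraries listed at 0), Cyp1a2 (-1.10 ± 0.19), Hod (-0.66 ± 0.12), the MHC class I gene H2-Q2 (-0.62 ± 0.11) and the merged Mup3 entry (-1.89 ± 0.35), with adjusted p between 0.0104 and 0.0433. The sulfotransferase Sult3a1 also passed (-0.85 ± 0.16, adjusted p = 0.0494), with male WT libraries listed at 0 and male ARE-Del libraries at 0.0287, 0.0847 and 0.024. Cyp1a2 fell in females (-0.61 ± 0.14) and rose in males (0.49 ± 0.14). The large rises of class II genes passed no interaction test over all genes (for example Cd74 -0.22 ± 0.35, adjusted p = 0.901).

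By camera, monocyte and macrophage markers (0.51 as the median interaction), chemokines and adhesion molecules (0.45), T cell markers (0.38), NK and cytotoxic markers (0.16), cell death genes (0.16) and the immediate early and heat shock genes (0.42) were more positive in females. With 1 library left out, these lists were called in 12, 12, 12, 6, 10 and 10 of 12 settings, so the NK result rested on single libraries. Low members can pass the filter through female ARE-Del alone, which favours this direction. Single members that passed over all genes were Ccl8 (1.08 ± 0.19) among chemokines and Itgax (1.02 ± 0.19) and Ms4a7 (0.50 ± 0.08) among monocyte markers. Adjusted over the list alone, 6 monocyte, 3 chemokine, 4 T cell, 3 immediate early, 0 NK and 0 cell death genes passed. More negative in females were female-biased liver genes (-0.79), sex steroid receptors and metabolism (-0.52), xenobiotic cytochrome P450 genes (-0.39), fatty acid synthesis (-0.31), cholesterol biosynthesis (-0.26), bile acid synthesis (-0.22), fatty acid oxidation and PPAR-alpha targets (-0.18), bile acid and bile lipid transport (-0.16) and hepatocyte identity genes (-0.09), called in 12, 12, 12, 9, 11, 12, 9, 12 and 9 of the 12. Over all genes, Cyp2b13 and Sult3a1 passed in the first of these lists and Cyp1a2 among P450 genes, and adjusted over the list alone 6 female-biased (1 the other way), 6 sex steroid, 6 P450, 4 bile acid synthesis and 3 transport genes passed, with 0 in the other 4 lists. Camera's adjusted p for the female-higher lists, in the order given, was 4.9e-07, 6.7e-06, 4.9e-04, 0.0439, 0.0182 and 0.0182, and with an estimated correlation adjusted p = 0.25, 0.16, 0.302, 0.546, 0.444 and 0.285. For the female-lower lists it was 3.9e-05, 4.9e-04, 4.9e-07, 0.0118, 0.00355, 0.0015, 0.0107, 0.00167 and 0.0118, and with an estimated correlation adjusted p = 0.16, 0.16, 0.16, 0.698, 0.71, 0.16, 0.71, 0.16 and 0.35. The IFN-gamma list (median 0.10, adjusted p = 0.386), MHC class II (0.17, adjusted p = 0.0972) and Kupffer markers (median 0.02, mean -0.09, adjusted p = 0.744) were among the 12 that did not pass.

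The interaction was called for 60 genes, 46 more positive and 14 more negative in females, and for 15 of 27 lists, 0 with an estimated correlation. At an unadjusted p below 0.05 there were 1231 genes. The count of 60 rested on single libraries, being 13, 17 and 36 without female WT 1, 2 and 3, 114 and 18 without female ARE-Del 1 and 3, 18, 11 and 12 without male WT 1, 2 and 3, and 16 without male ARE-Del 2. It was 65 without the library labelled female ARE-Del 2. Of the calls 76.7% were positive as deposited and 68.3% of 41 under median-of-ratios scaling, and 77.4% of 106 under quantile normalization.

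The comparison of WT females with WT males described the sex bias of the liver without the allele. Cyp2a4, a steroid hydroxylase, averaged 171 ± 28 RPKM in females and 0.0463 ± 0.0225 in males (female minus male log2 7.35 ± 0.16, adjusted p = 1.8e-11), and A1bg (7.22 ± 0.37) and Cyp2b13 (6.53 ± 0.12) were also higher in females. Cyp3a41a (527 ± 366 RPKM) and Sult3a1 (98.9 ± 18.2) were expressed in females and listed at 0 in all 3 male WT libraries. Higher in males were Cyp4a12a (-6.67 ± 0.27), Mup2 (-6.10 ± 0.41), the steroid dehydrogenase Hsd3b5 (-5.48 ± 0.38), Cyp4a12b (-5.24 ± 0.07) and Elovl3 (-5.18 ± 0.26), with adjusted p between 2.8e-13 and 1.8e-06. Xist differed by 5.18 ± 1.04, with female WT libraries between 32.95 and 38.15 RPKM. This SE uses the spread pooled over all 4 groups, including the library labelled female ARE-Del 2, and does not measure spread among WT livers. Ddx3y, Kdm5d, Uty and Eif2s3y were listed at 0 in all female WT libraries.

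All 17 female-biased genes were higher in WT females (median 4.73) and 15 of 16 male-biased genes higher in WT males (median -2.87; 16 adjusted over the list alone), and these lists held with either correlation (camera adjusted p = 2.7e-34 and 5.0e-37, and adjusted p = 0.0025 and 0.00885 with an estimated correlation). Camera also placed 7 lists higher and 1 lower in females, with 1 to 7 members of each called. The counts were 7 of 18 IFN-gamma-induced (8 adjusted over the list alone; median 0.35), 5 of 21 type I interferon (15; 0.33), 6 of 14 class I (7; 0.32), 4 of 12 Kupffer (9; 0.58), 3 of 20 cholesterol biosynthesis (5; 0.44), 1 of 12 stellate and matrix (2; 0.25) and 2 of 17 cell death genes (2; 0.16). Immediate early and heat shock genes were lower in females in 2 of 9 (2; -0.21). Over these 8 lists camera's adjusted p was 1.5e-04, 5.0e-05, 8.0e-04, 8.0e-04, 8.2e-04, 0.0244, 0.0399 and 0.0341, and with an estimated correlation the adjusted p was 0.67 to 0.70. Under median-of-ratios scaling 7 type I interferon and 6 Kupffer genes were higher. MHC class II genes did not pass, with 1 of 10 higher (median 0.25, adjusted p = 0.209). Of the 12 settings that leave out 1 library, 10, 9 and 10 called the stellate, cell death and immediate early lists. Limma called 1031 genes, 710 higher in females and 321 higher in males, and camera 10 lists, 2 with an estimated correlation. The count of genes was 655 without female WT 1 and 535 without male WT 1, and 68.9% were higher in females as deposited, 54.8% of 1421 under median-of-ratios scaling and 42.2% of 1395 under quantile normalization.

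In ARE-Del mice the sex comparison was led by nearly the same named genes. Cyp2a4 (7.07 ± 0.16), Cyp3a41a (7.52 ± 0.44), A1bg (6.14 ± 0.37), Sult3a1 (5.77 ± 0.12) and Cyp2b9 (5.67 ± 0.20) were higher in females, and Mup2 (-7.46 ± 0.41), Elovl3 (-6.63 ± 0.26), Cyp4a12a (-6.37 ± 0.27), Hsd3b5 (-5.69 ± 0.38) and Cyp4a12b (-5.41 ± 0.07) higher in males, with adjusted p between 1.9e-13 and 1.6e-06. Xist differed by 3.66 ± 1.04, with the library labelled female ARE-Del 2 near 0. All 17 female-biased genes (median 3.64) and all 16 male-biased genes (median -3.31) kept their bias (camera adjusted p = 6.3e-22 and 9.5e-28, and adjusted p = 0.012 and 0.0221 with an estimated correlation).

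Immune genes were higher in ARE-Del females than ARE-Del males. Low genes that are high in female ARE-Del alone can pass the filter, so the counts below lean that way. All 7 T cell markers (median 0.51), 10 of 12 monocyte markers (11 adjusted over the list alone; 0.81; Cybb 1.03 ± 0.18), 8 of 12 chemokine genes (9; 0.65; Cxcl9 1.03 ± 0.14) and 13 of 21 type I interferon genes (15; 0.43) were higher. So were 9 of 18 IFN-gamma-induced (11; 0.54), 4 of 14 class I (8; 0.28), 2 of 10 class II (3; 0.37), 5 of 6 NK (6; 0.38), 6 of 12 Kupffer (7 up and 1 down; 0.61), 6 of 12 stellate and matrix (7; 0.42), 4 of 7 cell cycle (7; 0.45), 9 of 24 acute phase (11; 0.57) and 9 of 17 cell death genes (11; 0.32), where the value after each count is that adjusted over the list alone and the other the median. Bile acid synthesis was lower in 6 and higher in 1 of 14 (6 and 1 adjusted over the list alone; -0.27), and fatty acid oxidation lower in 4 of 18 (4; -0.18). Under median-of-ratios scaling 6 class I and 7 acute phase genes were higher. Camera's adjusted p lay between 1.9e-06 and 0.0297 for these 15 lists, and with an estimated correlation between adjusted p = 0.12 and adjusted p = 0.633.

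Without the library labelled female ARE-Del 2 the acute phase, Kupffer and fatty acid oxidation lists no longer passed between the sexes in ARE-Del (adjusted p = 0.454, 0.165 and 0.10). With all libraries limma called 2370 genes, 1734 higher in females and 636 higher in males, and camera 17 lists, 2 with an estimated correlation. The gene count was 1522 without female ARE-Del 3 and 1453 without male ARE-Del 2. The share higher in females was 73.2% as deposited, 63.5% of 2758 under median-of-ratios scaling and 46.4% of 3010 under quantile normalization. Of the 710 genes higher in WT females, 439 were called the same way in ARE-Del, 2 the opposite way and 269 not at all, and of the 321 higher in WT males 205 were called the same way, 0 the opposite way and 116 not at all. Loss of a call does not show a changed bias. The interaction itself was called for 10 of the 710 and 14 of the 321. The median log2 difference went from 0.45 in WT to 0.33 in ARE-Del for the former and from -0.50 to -0.40 for the latter. These genes were chosen for their difference in WT, so some shrinkage follows from that choice. The 644 genes called the same way in both genotypes became 372 without male WT 1.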

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

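Of the tests in this part, those of Ddx3y, of list means over libraries (t tests, adjusted over 7), of expression level in males and of scaling were chosen only after the result was seen. The t tests replaced an exact permutation of sex labels, which counts the sex effect itself as chance and so says little where it does not pass. Its exact p was 0.23, 0.225, 0.665 and 0.01 for the monocyte, T cell, female-biased and P450 lists, and 0.05, 0.01 and 0.145 for monocyte markers set against endothelial, Kupffer and IFN-gamma lists.

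Xist was near 0 (0.0456 RPKM) in the library labelled female ARE-Del 2, far from the 33.0 to 45.6 of the other 5 female libraries. The Y-linked Ddx3y was at 0 in this library, which argues against a male liver under a female label. The X-linked genes that escape silencing, Kdm6a, Kdm5c, Ddx3x and Eif2s3x, were lower there by a median log2 of -0.53 against the other female ARE-Del libraries. Against their own groups the other female libraries gave -0.11 to 0.29. Of these the WT libraries gave -0.11 to 0.14, while the references of female ARE-Del 1 and 3 hold the library in question. Kdm6a (-0.56), Kdm5c (-0.50) and Eif2s3x (-0.70) were lower there, but Ddx3x (-0.19) was lowered less than in female WT 2 (-0.37). The median argues against a failed measurement of Xist alone. A liver with a single X chromosome may explain the low Xist and the low median. This is a hypothesis from 1 library of unknown karyotype. Without this library 3163 genes and 22 lists were called in females, with the acute phase list lost (camera adjusted p = 0.345).

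The genotype effect differed between the sexes for 60 genes by the interaction test. The values more positive in females were Clstn3 1.35 ± 0.12, Lcn13 2.18 ± 0.28 (female WT listed at 0), H19 1.48 ± 0.19, Col4a3 0.82 ± 0.10, Tsc22d1 0.77 ± 0.11, Mtnr1a 0.70 ± 0.09, Aatk 0.56 ± 0.08, Unc119 0.56 ± 0.08, Serpina1e 3.49 ± 0.54, Ccbl2 1.10 ± 0.21, Ccl8 1.08 ± 0.19, Itgax 1.02 ± 0.19, Ms4a7 0.50 ± 0.08, Tlr1 0.75 ± 0.13 and Tlr9 0.42 ± 0.08. Those more negative were St3gal6 -0.51 ± 0.07, Pcp4l1 -1.26 ± 0.20, Cyp2b13 -1.05 ± 0.17 (male ARE-Del listed at 0), Cyp1a2 -1.10 ± 0.19, Hod -0.66 ± 0.12, H2-Q2 -0.62 ± 0.11, the merged Mup3 entry -1.89 ± 0.35 and Sult3a1 -0.85 ± 0.16 (male WT listed at 0). Of these 23 named genes, 18 were called without female ARE-Del 2, 8 in every setting with 1 library left out, 12 in at most 6 of those 12 settings and 6 in every alternative. Of 100 splits that exchange sex labels within genotype, 9 gave at least 60 genes, the real one included, and 19 gave at least 15 lists (highest other 19), so chance is not excluded by this count. The highest other split, 3519 genes, exchanged the sex labels of all ARE-Del libraries. That split turns the interaction into the summed sex effect, a structure of the samples, so these splits are not a clean comparison.

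The lists that differed between sexes by camera were, as median interactions, monocyte and macrophage markers 0.51, chemokines and adhesion molecules 0.45, the immediate early and heat shock genes 0.42, T cell markers 0.38, NK and cytotoxic markers 0.16 and cell death genes 0.16. In the other direction they were female-biased liver genes -0.79, sex steroid receptors and metabolism -0.52, xenobiotic cytochrome P450 genes -0.39, fatty acid synthesis -0.31, cholesterol biosynthesis -0.26, bile acid synthesis -0.22, fatty acid oxidation and PPAR-alpha targets -0.18, bile acid and bile lipid transport -0.16 and hepatocyte identity genes -0.094. None of the 15 passed with an estimated correlation, and without the library labelled female ARE-Del 2 the immediate early (adjusted p = 0.0583) and fatty acid oxidation lists (adjusted p = 0.108) did not pass.

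T cell and monocyte markers rose more in females by camera, and in both lists the larger adjusted p without the library labelled female ARE-Del 2 was 2.1e-05, which argues against that library as the source. Over libraries the mean interaction was 0.52 ± 0.22 for monocyte markers and 0.33 ± 0.13 for T cell markers (SE, adjusted p = 0.0623 for each), so chance between libraries is not excluded. A lower share of hepatocytes would raise all other cell types alike. Set against endothelial markers the monocyte interaction was 0.69 ± 0.26 (t test, adjusted p = 0.0623), which leaves that open. Set against Kupffer markers it was 0.60 ± 0.16 (t test, adjusted p = 0.0163), so these lists did not rise alike in these libraries. Camera had called the monocyte list on these same libraries, so this value does not exclude a lower share of hepatocytes. A change in the Kupffer cells themselves also stays open. A larger IFN-gamma response in females cannot be told apart, since the difference to the IFN-gamma list was 0.44 ± 0.29 (adjusted p = 0.162), and sex hormones were not tested.

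By camera, the genotype effect on female-biased and P450 genes was more negative in females than in males. As deposited neither list's median fell in males, though both were negative after quantile normalization. Without the library labelled female ARE-Del 2 the larger adjusted camera p was 7.9e-06, which argues against that library as the source. The median interaction over all genes was 0.00043, which argues against a scaling shift common to all genes. It cannot show a shift that depends on expression level. Over libraries the mean interaction was -0.45 ± 0.11 for P450 genes (t test, adjusted p = 0.0163) and -0.56 ± 0.31 for female-biased genes (adjusted p = 0.125). Chance is not excluded for the latter. Nor is it for P450 genes, a list that camera had called on these same libraries, with adjustment over 7 tests alone. Only 2 of 17 female-biased genes reached 5 RPKM in male WT, so levels in males too low to fall may explain their difference. All 16 members of the P450 list, which also holds Por, Nr1i2 and Nr1i3, reached it (the lowest, Nr1i2, at 12 RPKM). The lowest cytochrome P450 entry was Cyp3a13 at 28.3 RPKM. These levels argue against low levels in males for that list. A loss of P450 transcripts in females without a like fall in males stays open as a hypothesis from the data it was found in. Sex hormones were not tested.

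In the other comparisons 3 against 3 libraries make 10 splits, too few for a share under 0.05. The real value and the highest of the other splits were 3306 and 1 genes and 20 and 16 lists in females, 2272 and 0 genes and 14 and 15 lists in males (5 splits with as many lists), 1031 and 1 genes and 10 and 10 lists between sexes in WT (4 splits), and 2370 and 0 genes and 17 and 18 lists between sexes in ARE-Del (2 splits). For genes, and for lists in females, only 1 split, the real one, gave as many.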

How the results depend on the processing

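The alternatives in this part were all planned, and none was added after the results were seen. The counts of genes and lists kept within 1.5 times their value except as follows, and for these the cause was not tested unless a construction is named.

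With a log2 fold change of at least 1 also required, by construction fewer genes passed: 450 in females, 260 in males, 19 in the interaction, 154 between sexes in WT and 179 in ARE-Del. With an estimated correlation the called lists were 0, 0, 0, 2 and 2. The interaction gave 14 genes with a pseudocount of 0.1, 30 with no filter, 32 with RPKM of at least 1, 106 with quantile normalization, 32 with a replicate block and 153 with library weights.

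Leaving out 1 library, which also lowers the number of samples, gave 2479 (without female ARE-Del 3) to 3278 genes in females and 19 to 22 lists. In males it gave 1271 (without male WT 1) to 2480 genes and 11 to 14 lists. For the interaction it gave 11 (without male WT 2) to 114 genes (without female ARE-Del 1) and 12 to 18 lists, with 13, 17 and 36 genes without female WT 1, 2 and 3, 18 without female ARE-Del 3, 18 and 12 without male WT 1 and 3 and 16 without male ARE-Del 2. Between sexes it gave 535 (without male WT 1) to 1126 genes in WT, with 655 without female WT 1, and 1453 (without male ARE-Del 2) to 2498 in ARE-Del, with 1522 without female ARE-Del 3. Lists ran from 8 to 11 and from 15 to 18. The overlap of female and male effects ran from 1099 (without male WT 1) to 1778, and the retained sex bias from 372 (without male WT 1) to 724. Without the library labelled female ARE-Del 2 there were 3163 genes in females, 65 in the interaction and 2231 between sexes in ARE-Del.

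Of 288 results for named genes, 267 kept their direction and side of the threshold with a pseudocount of 0.1, 245 with no filter, 266 under median-of-ratios scaling, 256 under quantile normalization and 276 with library weights. Of 76 list results 69 did so under median-of-ratios scaling, 62 under quantile normalization and 4 with an estimated correlation. Among genes called in the deposited scale, 39 of 3306 in females and 17 of 2272 in males had the opposite sign under quantile normalization, none of them called there.

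Among these 288 results for named genes, signs reversed in 12, of which 0 were called with the deposited scaling and all libraries. The range after each is that with 1 library left out, so it need not hold a quantile value. In females these were Alas2 (0.049 without female WT 3; range -0.37 to 0.049), Cxcl11 (-0.049 with quantile normalization and -0.0015 without female WT 3; -0.0015 to 0.28), Hba-a1 (0.11 and 0.021 without female WT 3 and ARE-Del 3; -0.43 to 0.11) and Hbb-yandHbb-b1 (0.055 without female WT 3; -0.53 to 0.055). In males they were Akr1c6 (0.0044 without male ARE-Del 2; -0.15 to 0.0044), Cyp39a1 (-0.078; -0.078 to 0.47) and Cyp3a11 (-0.095; -0.095 to 0.29) without the same library, S100a8 (-0.10 without male ARE-Del 1; -0.10 to 0.26), Slco1a1 (0.044 without male WT 1; -0.21 to 0.044), Cxcl11 (-0.11 with quantile normalization, -0.029 without male WT 1, -0.025 without male ARE-Del 3; -0.029 to 0.12), and under quantile normalization Cdc2a (-0.026) and Vwf (-7.9e-04).

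Keeping the highest entry per symbol could not be run because identifiers are unique, and the fit with only the groups compared has no interaction value.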

Other observations

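The families in this part, 22 in all, were looked at after the gene results were seen, so all their tests were chosen after the result, while the test of genes near Ifng was written before its result was seen.

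Innate sensing genes moved with genotype. Of 12 tested Toll-like receptors 11 rose in females (family median log2 0.73, camera adjusted p = 6.9e-06 over 22 families) and 10 rose in males (0.43, adjusted p = 3.8e-04). Tlr1 rose by 1.51 ± 0.10 in females and 0.76 ± 0.10 in males, Tlr2 by 1.41 ± 0.13 and 0.99 ± 0.13, Tlr4 by 0.71 ± 0.06 and 0.51 ± 0.06, while Tlr5 fell (-0.47 ± 0.08 and -0.46 ± 0.08). The family median interaction was 0.33 (adjusted p = 3.2e-07). With an estimated correlation the lowest adjusted p of any family was 0.526 in females, 0.324 in males and 0.372 in the interaction, so no family passed.

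Lysosomal cathepsins rose in 8 of 11 in each sex (Ctsb 0.67 ± 0.11 in females and 0.62 ± 0.11 in males, Ctsc 0.96 ± 0.13 and 1.09 ± 0.13), and C-type lectins in 8 of 13 in each (Clec7a 1.96 ± 0.22 and 1.45 ± 0.22, Clec4a1 2.04 ± 0.19 and 1.41 ± 0.19). UDP-glucuronosyltransferases fell in 4 of 6 in females (family median -0.60; Ugt2b34 -0.65 ± 0.11, Ugt2b36 -0.58 ± 0.10) and in 0 in males, or in 6 and 1 under median-of-ratios scaling. The family median interaction was -0.45 (adjusted p = 2.0e-04). Complex I genes fell in 3 of 36 in females and 1 in males as deposited, and in 26 and 6 under median-of-ratios scaling. Under that scaling other mitochondrial families fell too. Mitochondrial ribosomal genes fell in 23 of 74 in females and 14 in males, ATP synthase genes in 13 of 16 and 4. Complex IV genes fell in 6 of 13 and 3. In females 1 mitochondrial ribosomal gene and 1 ATP synthase gene rose.

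DNA near the modified Ifng locus carried over from another strain was a hypothesis for genotype differences near the gene. Of the 100 tested genes nearest to Ifng, 50 on each side, 17 (17%) were called in the same direction in both sexes, against 17.2% of 7794 other genes (Fisher's exact p = 1), which argues against a local excess of calls.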
